A study of Mus musculus with 4 samples.

How the data were processed

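Total RNA from cultures of 2 mouse keratinocyte lines, MK1 and MK2, was sequenced after library construction with an Illumina TruSeq RNA kit, per the labels' protocols. The series' design text gives 2 biological replicates of each line, so that 4 libraries formed 2 groups of 2. The labels give no passage number, sex, strain or culture day, and nothing that ties a replicate of 1 line to a replicate of the other.

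The deposited table held raw read counts per gene, which the authors had not normalised. Per the file headers, reads in TopHat alignments were assigned to exons and summed by gene name with featureCounts 1.4.6-p4 against the UCSC mm10 gene annotation. Per the submitters' processing notes, the tools were TopHat2 2.0.13, Bowtie2 2.2.6, featureCounts 1.5.0 and DESeq2 1.10.1, so the header and the notes differ in the featureCounts version. The command in the header set no option for strand, read pairs or reads with several alignments. Counts of overlapping genes, of antisense partners and of genes with near-identical copies (Krt6a and Krt6b, Krt14, Krt16 and Krt17, the Sprr2 and Lce families, the H2 genes, and pseudogenes) are therefore uncertain. The header's command calls the second line's alignments MKU, whereas the column names call them MK2; columns were matched to samples by the names that occur in the sample titles. No count column was left without a sample (0 columns).

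The table had 23420 gene rows, of which 6644 had 0 counts in all 4 libraries. Names of 27 rows had been turned into calendar dates, 2 of them used for a pair of rows each, and these rows kept their counts but were not interpreted. No row lacked a gene name (0 rows). Gene positions on mm10 came from the deposited table. Total counts per library were 30261111 and 26693849 for MK1 and 25237391 and 28601806 for MK2. A gene with 0 counts in a library had a level of at most 3 counts, between 0.0991 and 0.119 CPM. Such floors and all ratio intervals cover counting error only. CPM are read counts per 1e6 counts of the library. Floors behind fold changes were 3 counts over both libraries of a line.

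Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Low-count genes were removed with filterByExpr (minimum count 10), libraries were scaled with TMM, and MK2 was compared with MK1 by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05, two-sided. A second test, glmTreat, asked for changes beyond a log2 fold change of 1. CPM values used TMM-scaled library sizes and are given as mean ± SD over the 2 cultures of a line, and TPM from the deposited gene lengths served only to order genes by abundance. Gene lists were compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and again with a correlation estimated from the data. The 38 lists covered keratinocyte states, other cell types, signalling, stress, metabolism, Hox, imprinted and sex-linked genes, and 33 of them had the 5 tested members that camera needed. Of 716 listed symbols, 9 were matched through a synonym and 5 were not found, among them Flg, which was not analysed here. The same test was run on the genes of each of 20 chromosomes, and medians were taken over runs of 50 neighbouring tested genes.

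The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule named a fixed set of keratinocyte, cell-cycle and sex-chromosome genes, the 10 largest changes in each direction at 10 CPM or more in the higher line with non-overlapping cultures, up to 4 called members of each list at 1 CPM or more (or its most abundant member), and the 10 most abundant genes by TPM. Genes named outside that rule are said to have been chosen after their values were seen.

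The procedure was tested on simulated data. Counts were drawn for the same genes, means and library sizes in the comparison of 2 against 2 libraries, with 100 genes changed by 2-fold and 100 by 4-fold. Of these, 88% and 100% were recovered, and 0.0512% of 11719 unchanged genes were called. A simulated shift of chromosome 13 and a simulated shift of 1 list were also recovered, and 0 of 32 unshifted lists were called. Genes were drawn independently, so the simulation cannot show how list and chromosome calls behave when genes are correlated. The spread between simulated libraries depended on expression level alone. Genes changed by 2-fold or 4-fold were picked from well-counted genes, and changed genes were far fewer than those called in the data.

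Replicates were compared before averaging. The chi-square per gene between replicates had a median of 2.88 in MK1 and 4.28 in MK2 over genes with at least 20 counts, above counting noise, so no library had been counted a second time. Alternatives covered scaling (DESeq2 size factors, library size alone, upper quartile), count filters, each library left out in turn, the replicate number as a block, gene-length and GC trends, thinning to the smallest library, DESeq2 1.42.0 and limma-voom as tools, other thresholds, and estimated correlations or random lists for the list tests. GC content came from the GENCODE annotation of the same mouse assembly and covered 99.1% of the tested genes. A crossed block, the GC trend, subtraction of chromosome medians and a list without MHC class II genes were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.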

Results

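Gene expression was measured by RNA sequencing in 2 mouse keratinocyte lines, MK1 and MK2, with 2 biological replicate cultures of each. Keratinocytes are the epithelial cells that build the epidermis, and the series belongs to work on the targets of p63, the transcription factor that maintains stratified epithelia, in mouse and human skin. The comparison that the design allows is MK2 against MK1, and every fold change is given as MK2 minus MK1. Libraries held 25237391 to 30261111 counts, and levels are given as CPM, read counts scaled to a common library size. Each line stood for itself alone, so p-values refer to the spread between cultures of these lines and not to mouse keratinocyte lines in general.

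Both lines expressed the basal keratinocyte genes at high levels. Krt5 (chromosome 15, 101707070 to 101712891, mm10), the type II keratin of basal cells, stood at 8032 ± 112 CPM in MK1 and 7943 ± 1300.1 CPM in MK2 (SD, n = 2 cultures of each line, as for every SD below). Its partner Krt14 (chromosome 11, 100203162 to 100207510) stood at 8763 ± 76.6 and 8387 ± 1119 CPM. Trp63, which encodes p63, stood at 217 ± 4.94 and 261 ± 6.32 CPM. None of these 3 genes passed the test (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.925, 0.681 and 0.0587), and the sign of the small Krt5 and Krt14 differences depended on the setting. Of 18 basal markers, 17 had 10 CPM or more in both lines, 3 rose, 4 fell and 11 did not pass, with the same counts adjusted over the list alone. The integrins Itgb1 and Itga6 rose by 1.03 and 0.83 on the log2 scale, while Col17a1, a hemidesmosome collagen, fell by 1.06 and the laminin chain Lamb3 by 0.76. The list as a whole was not called (camera adjusted p = 0.964; median -0.04 and mean 0.04 differed in sign). Vim, an intermediate filament of mesenchymal cells, stayed below 1 CPM in every library, and Krt1, a keratin of suprabasal cells, had 0 counts in all 4.

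The lines differed widely beyond that shared basal programme. Of 12479 genes tested, 3235 were higher and 3575 lower in MK2 at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), together 54.6%. Beyond 2-fold, glmTreat called 405 genes higher and 1257 lower. With MK1 replicate 1 left out the count of called genes was 3716, and with MK1 replicate 2 left out it was 4369, and the count beyond 2-fold was 985 without MK1 replicate 1. Across genes, Spearman correlations were 0.995 and 0.992 between replicates and 0.917 to 0.927 between lines, with genes not being independent replicates. At a mean of 10 CPM or more in 1 line, 5 genes were without a count in MK1 and 8 without a count in MK2.

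The largest increases were led by Slc32a1, the vesicular GABA transporter (chromosome 2, 158610758 to 158615747), which had 0 counts in MK1 and 87.1 ± 21.4 CPM in MK2, at least 1680-fold higher. Bmp7, a secreted BMP ligand (chromosome 2, 172869687 to 172940293), had 0 counts in MK1 and 15.3 ± 4.11 CPM in MK2, at least 295-fold higher. Krtdap, a keratinocyte differentiation protein, rose from 0.310 ± 0.299 to 374 ± 74.8 CPM, and the serpin Serpinb6c rose by 9.60 on the log2 scale. The predicted gene Gm5779 stood at 56.1 and 56.2 CPM in MK2 with 6 counts in MK1, and its reads may be shared with copies. Cxcl5, a neutrophil chemokine, was uneven, with 1.51 and 21.2 CPM in the MK2 cultures and 1 count in MK1, and its call ended without MK1 replicate 1 (adjusted p = 0.0766) or MK1 replicate 2 (adjusted p = 0.0588). The other 4 of the 10 largest increases were Y-linked. The largest decreases included Cldn6, a tight-junction claudin (chromosome 17, 23679365 to 23682446), with 124 ± 5.96 CPM in MK1 and 0 counts in MK2, at least 2199-fold lower. Pmp22, a membrane protein best known from myelin, fell from 74.5 ± 9.49 CPM to 0 counts, at least 1321-fold. Fam111a, Tlr5, Pcdhga11, H2-Ab1, 0610007N19Rik and Zfp395 also had 0 counts in MK2, and their lower bounds ran from 186-fold for Zfp395 to 702-fold for Fam111a. Pxdn, a peroxidase of the extracellular matrix, had 2 counts in MK2 and was 3491-fold lower (95% counting interval 966 to 28829).

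Keratins of simple epithelia were lower in MK2. All 4 tested members of that list fell (4 adjusted over the list alone), too few for a list test with the main count filter. With no low-count filter the list was large enough for camera and was called. Krt8 (chromosome 15, 101996711 to 102004342) fell from 1383 ± 15.5 to 9.94 ± 0.115 CPM and its partner Krt18 (chromosome 15, 102028216 to 102032026) from 263 ± 10.8 to 1.92 ± 0.0231 CPM. Krt7 (chromosome 15, 101412403 to 101427806) fell from 2106 ± 71.8 to 17.3 ± 3.86 CPM and Krt20 fell by 4.98 on the log2 scale. Adjusted p lay between 2.00e-06 and 3.84e-05 in edgeR's quasi-likelihood test. Krt5 lies between Krt7 and Krt8 on the chromosome. In the opposite direction, Krt17, a keratin induced in wounded epidermis (chromosome 11, 100256217 to 100260989), rose from 3.48 ± 0.238 to 828 ± 103 CPM, and Krt6a, another wound keratin whose reads may be shared with Krt6b, rose by 0.81 on the log2 scale. These were the 2 of 4 tested wound and stress keratins that rose (3 adjusted over the list alone).

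**Figure D1:**
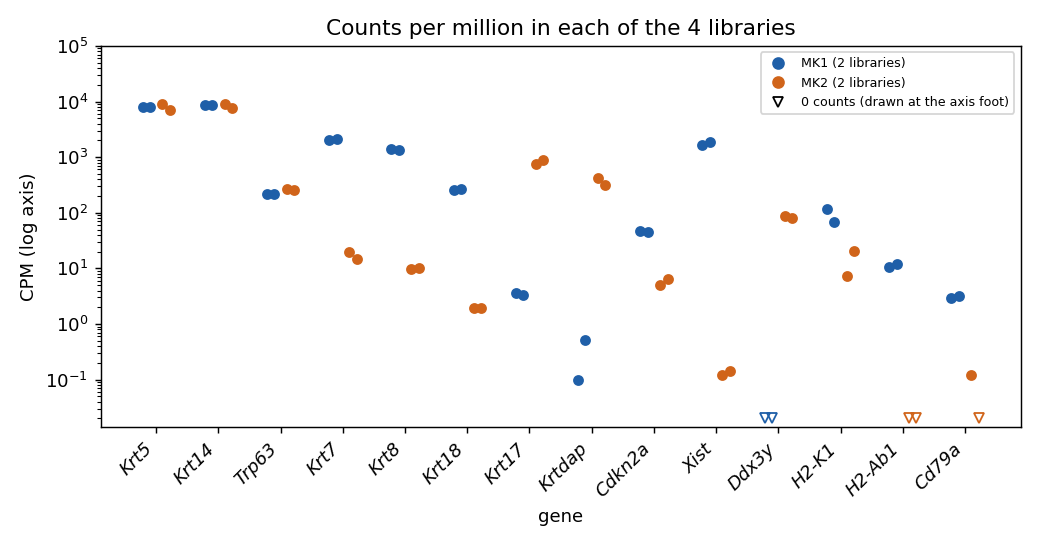
CPM (log axis) of 14 genes in each of the 4 libraries, MK1 in blue and MK2 in orange, with open triangles at the foot for 0 counts. Krt5, Krt14 and Trp63 lie at similar levels in both lines, Krt7, Krt8, Krt18, Cdkn2a, Xist, H2-K1, H2-Ab1 and Cd79a lie lower in MK2, and Krt17, Krtdap and Ddx3y lie higher.

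Several genes of epidermal differentiation were higher in MK2, although neither differentiation list passed camera. Of 11 tested granular and cornified genes, 7 rose and 2 fell (camera adjusted p = 0.139), and of 11 tested spinous genes, 6 rose and 2 fell (camera adjusted p = 0.211), with the same counts adjusted over each list alone. Both lists were called higher against random lists matched on expression, which ignore correlation between genes (adjusted p = 0.00110 and 0.00825). Abca12, a lipid transporter of the skin barrier, rose to 149 ± 18.2 CPM, by 4.96 on the log2 scale, and Ivl, the cornified-envelope protein involucrin, from 10.5 ± 1.83 to 57.7 ± 12.6 CPM. The transcription factor Klf4 rose by 0.93 on the log2 scale, and Notch3 fell by 1.68. Klf4 lies on chromosome 4 in a run of 50 neighbouring tested genes whose median was 0.91. Its rise was thus about that of its neighbourhood. Terminal markers stayed low: Lor (loricrin) had 2 counts in MK1 and 0.854 CPM in MK2, and Krt10 stood at 2.24 and 4.07 CPM, its call ending without MK1 replicate 1 (adjusted p = 0.118), MK1 replicate 2 (adjusted p = 0.0978) or MK2 replicate 1 (adjusted p = 0.0751), and in DESeq2 (adjusted p = 0.0549). Tgm1 and Asprv1, at 2.21 and 1.23 CPM in MK2, lost their calls without MK1 replicate 1 (adjusted p = 0.0949 and 0.0614). Among 32 tested genes listed as p63 targets, 7 rose and 14 fell, and the list was not called (camera adjusted p = 0.411), but was called lower against random lists (adjusted p = 0.0445). Bmp7, Pthlh and Fgfr3 were higher, and Zfp750, a regulator of terminal differentiation, fell from 49.5 ± 7.18 to 5.09 ± 1.24 CPM.

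Genes of tight junctions were lower in MK2. Of 13 tested, 10 fell and none rose (11 lower adjusted over the list alone), with a list median of -1.0 (camera adjusted p = 0.00153; adjusted p = 0.698 with an estimated correlation). Between cultures of 1 line, replicate 2 minus replicate 1, the list median was -0.13 in MK1 and 0.49 in MK2 on the log2 scale. Cldn4 fell from 708 ± 168 to 122 ± 89.8 CPM and Marveld3 had a log2 change of -1.57. Tjp3 was near 1 CPM and lost its call without MK1 replicate 1 (adjusted p = 0.0591). Of 13 tested genes of desmosomes and adherens junctions, 7 fell and 2 rose, and the list was not called (camera adjusted p = 0.411; median -0.44 and mean 0.29 differed in sign), but was called lower against random lists (adjusted p = 0.0493). Cdh1, which encodes E-cadherin, fell from 808 ± 124 to 367 ± 37.1 CPM, and Dsg2 and Pkp2 had log2 changes of -1.61 and -0.89, whereas the desmosomal cadherin Dsc2 went from 0 counts to 2.14 ± 1.01 CPM, at least 41.7-fold higher. Itgb4, a hemidesmosome integrin, was not called (adjusted p = 0.0865), but was called lower without MK2 replicate 2 (log2 change -0.76, adjusted p = 0.00119), with no low-count filter (adjusted p = 0.0334), with the crossed block (adjusted p = 0.00336) and in DESeq2 (adjusted p = 0.0476).

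MK1 carried Xist RNA and MK2 carried Y-linked transcripts. Xist, the RNA that silences an X chromosome in female cells (chromosome X, 103460373 to 103483233), stood at 1658 and 1880 CPM in the MK1 cultures and at 0.119 and 0.141 CPM in MK2, where both libraries together held 7 counts. The Y-linked genes Ddx3y, Kdm5d and Eif2s3y had 0 counts in MK1, and Uty had 1. In MK2 these 4 genes stood between 31.0 and 86.7 CPM, and Ddx3y (chromosome Y, 1260715 to 1286613) was at least 1599-fold higher. The list of 9 tested sex-linked genes had 5 rising and 2 falling and was not called (camera adjusted p = 0.104), except with chromosome medians subtracted, an alternative added after the data had been seen (adjusted p = 0.0371).

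The CDK inhibitor locus Cdkn2a (chromosome 4, 89274473 to 89294619), which encodes p16 and p19ARF, fell from 46.7 ± 1.68 to 5.69 ± 1.08 CPM, while Trp53, which encodes p53, stood at 143 and 186 CPM and was not called (adjusted p = 0.0741). Trp53 was called higher without MK2 replicate 1 (log2 change 0.59, adjusted p = 0.00326), with no low-count filter (log2 change 0.38, adjusted p = 0.0413) and with the crossed block (log2 change 0.37, adjusted p = 0.0277). Transcripts listed as p53 targets were lower together: 21 of 23 fell and none rose, also when adjusted over the list alone, with a median of -0.97 (camera adjusted p = 1.10e-05; adjusted p = 0.619 with an estimated correlation). Btg2, an antiproliferative gene (chromosome 1, 134074865 to 134079155), fell from 118 ± 6.86 to 25.5 ± 0.179 CPM, and Eda2r, Bbc3 and Trp53inp1 had log2 changes of -1.93, -1.93 and -1.89. Chosen after their values were seen, Cdkn1a and Mdm2 had log2 changes of -1.33 and -1.58. Proliferation genes were higher: 20 of 28 rose and 1 fell, with the same counts adjusted over the list alone and a median of 0.63 (camera adjusted p = 3.42e-04; adjusted p = 0.748 with an estimated correlation). Between cultures of 1 line, replicate 2 minus replicate 1, the median of the proliferation list was 0.25 in MK1 and -0.19 in MK2 on the log2 scale. The mitotic kinase Aurka rose from 52.9 ± 11.6 to 167 ± 14.1 CPM, and Bub1 and Mcm5 rose by 1.14 and 1.13, whereas E2f1, chosen after its value was seen, was the member that fell (by 0.58). In the list on senescence and immortalisation 5 of 15 rose and 6 fell (camera adjusted p = 0.869; median 0.16 and mean -0.68 differed in sign). Tert, the telomerase subunit, fell from 2.81 ± 0.246 to 0.183 ± 0.0903 CPM.

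Antigen-presentation and leukocyte-marker transcripts were lower in MK2, and B-lymphocyte transcripts were present in both MK1 libraries. Of 18 tested MHC and antigen-presentation genes, 15 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -2.08 (camera adjusted p = 1.10e-05; adjusted p = 0.619 with an estimated correlation). The class II genes H2-Ab1 (chromosome 17, 34263227 to 34269418) and H2-Aa stood at 11.3 ± 0.888 and 8.31 ± 0.0620 CPM in MK1 and had 0 counts in MK2, at least 200.1-fold and 148-fold lower, and H2-Eb1 and the class II activator Ciita had 1 count each in MK2. Without the class II genes and Ciita, an alternative added after the data had been seen, 11 of 14 members fell and 1 rose (median -1.69, camera adjusted p = 0.00113; adjusted p = 0.698 with an estimated correlation). Among them, chosen after their values were seen, the class I gene H2-K1 went from 92.7 to 13.7 CPM and the peptide transporter Tap1 from 48.5 to 19.1 CPM. Of 16 listed leukocyte markers, 6 had enough counts to be tested, and all 6 fell (6 adjusted over the list alone). Their median was -4.98 (camera adjusted p = 0.00113, and 0.698 with an estimated correlation). Cd74, the class II invariant chain, stood at 17.8 ± 0.168 CPM in MK1 with 3 counts in MK2, and Ptprc, which encodes the leukocyte antigen CD45, at 2.59 ± 0.292 CPM with 1 count in MK2. Cd74, Ptprc and Laptm5 (1 count in MK2) passed the count filter through MK1 alone, so they could only be found lower in MK2.

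Chosen after these values were seen, the B-cell genes Cd79a, Cd79b and Ms4a1 stood at 2.93 and 3.13, 2.34 and 2.64, and 1.61 and 1.23 CPM in the MK1 replicates, and at 0 to 0.119 CPM in MK2. The T-cell gene Cd3e had at most 0.0372 CPM in any library. Of 13 tested interferon-response genes, 8 fell and 1 rose, with the same counts adjusted over the list alone and a median of -0.71 (camera adjusted p = 0.0340; adjusted p = 0.698 with an estimated correlation). That list call also ended without MK2 replicate 1 (adjusted p = 0.0556), without MK2 replicate 2 (adjusted p = 0.0661), with the replicate block (adjusted p = 0.0629, and 0.0616 with the length trend removed) and against random lists (adjusted p = 0.305). The RNA sensor Ifih1 (chromosome 2, 62595793 to 62646255) fell by 5.92 on the log2 scale to 0.243 ± 0.00601 CPM, and Parp14 from 3.53 ± 0.258 to 0.130 ± 0.0155 CPM. Irf7 fell by 1.45, a call that ended without MK1 replicate 1 (adjusted p = 0.0508) or MK1 replicate 2 (adjusted p = 0.0652).

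Hox and imprinted genes were lower in MK2. Of 26 tested Hox genes, which encode positional transcription factors, 18 fell and 1 rose, with the same counts adjusted over the list alone and a median of -1.14 (camera adjusted p = 2.31e-04; adjusted p = 0.619 with an estimated correlation). Hoxc5, Hoxd8, Hoxd9 and Hoxc9 stood at 3.39 to 4.66 CPM in MK1 and had 0 counts in MK2, at least 60.1-fold to 82.3-fold lower. Hoxc13, a regulator of hair keratins, rose from 0.190 ± 0.0575 to 7.85 ± 2.17 CPM. Of 17 tested imprinted genes, 10 fell and 2 rose (11 and 2 adjusted over the list alone), with a median of -1.18 (camera adjusted p = 0.00380; adjusted p = 0.698 with an estimated correlation). Sgce and Peg10, neighbours on chromosome 6, had 7.74 ± 2.11 and 1.94 ± 1.16 CPM in MK1 and 0 counts in MK2, and Grb10 and Ndn stood at 26.5 and 7.52 CPM in MK1 with 3 and 1 counts in MK2. The 2 members that rose were Mest and Phlda2, named after their values were seen.

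Cholesterol synthesis genes were lower in MK2. Of 23 tested, 18 fell and none rose (20 and 1 adjusted over the list alone), with a median of -0.86 (camera adjusted p = 0.00150; adjusted p = 0.748 with an estimated correlation). Tm7sf2, Lss and Idi1 had log2 changes of -3.10, -2.03 and -1.78. These genes also differed between cultures of 1 line: replicate 2 minus replicate 1 had a list median of 0.27 in MK1 and 0.49 in MK2. With a correlation estimated from the data, none of the 9 list calls held (0 of 33 lists, lowest adjusted p = 0.619). Setting genes with 0 counts in 1 line at their bound left each of these list medians as given.

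**Figure D2:**
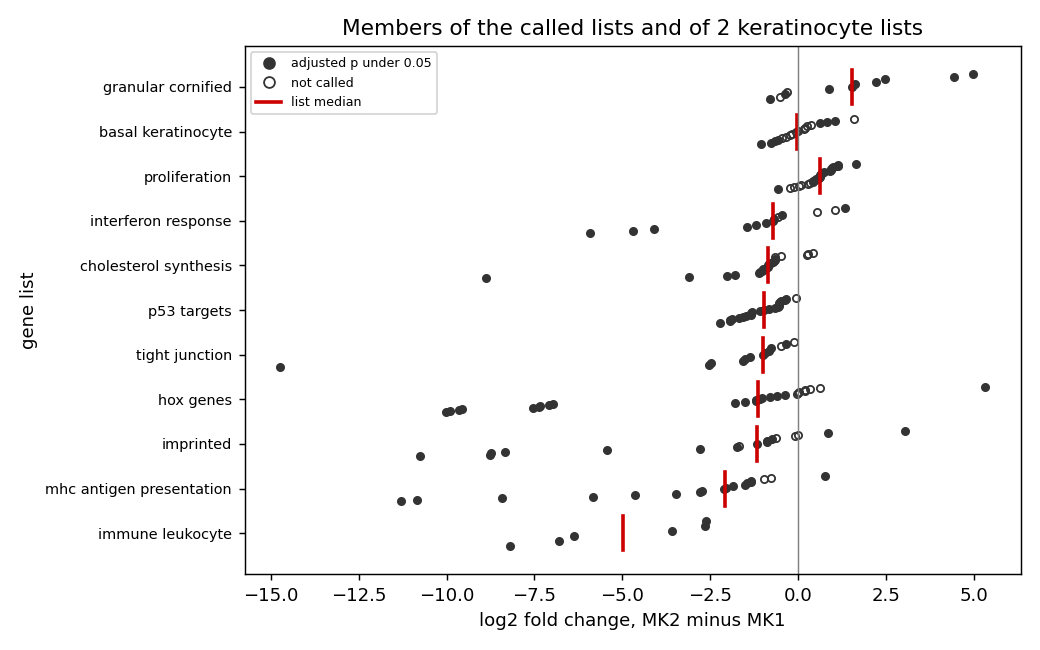
Log2 fold changes (MK2 minus MK1) of the tested members of the 9 called lists and of 2 keratinocyte lists that were not called, with filled points for an adjusted p under 0.05, open points for genes not called and a red bar at the list median. Fitted values of genes with few counts in 1 line depend on the prior count. The medians run from -4.98 for leukocyte markers to 0.63 for proliferation among the called lists.

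Whole chromosomes differed in level between the lines. Of 20 chromosomes, 9 were called by camera with Benjamini-Hochberg adjustment: chromosomes 4, 2, 8 and 16 were higher in MK2, with median log2 fold changes of 0.37, 0.36, 0.29 and 0.28, and chromosomes 13, 10, 12, 14 and 9 were lower, with medians of -0.41, -0.33, -0.25, -0.24 and -0.23. With an estimated correlation none of these calls held (0 of 20 chromosomes, lowest adjusted p = 0.0605). The call of chromosome 12 ended with no low-count filter (median -0.21, adjusted p = 0.0599), and chromosome 15 was called lower without MK1 replicate 1 (median -0.15, adjusted p = 0.0408) and chromosome X lower with the GC trend removed (median -0.13, adjusted p = 0.0488), an alternative added after the data had been seen. On chromosome 13, 76.6% of 461 tested genes lay below 0 (adjusted p = 1.88e-05), and on chromosome 4, 32.8% of 775 (adjusted p = 8.42e-05). Along chromosome 4 the shift was not uniform: the first 10 runs of 50 genes, from 3.5 to 130.4 Mb, had medians of 0.32 to 0.91, and the 5 full runs after 130.5 Mb had medians of -0.05 to 0.04, and the last 25 tested genes, from 155.8 to 156.2 Mb, had a median of 0.32. Cdkn2a lies inside the raised part. On chromosome 2, the last 29 tested genes, from 180.6 to 181.9 Mb, had a median of -1.09 and the full run from 148.4 to 153.8 Mb had a median of -0.46, against 0.36 for the chromosome. On chromosome 9, the first 3 runs had medians of 0.05 to 0.15, against -0.23 for the chromosome.

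**Figure D3:**
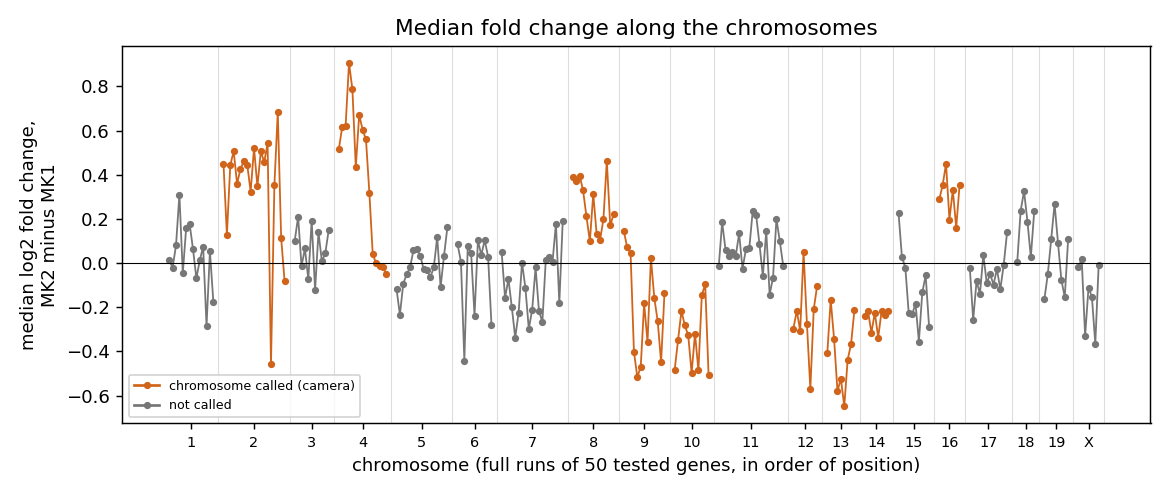
Median log2 fold change (MK2 minus MK1) in full runs of 50 neighbouring tested genes along each chromosome, with called chromosomes in orange and the others in grey. Chromosome 4 falls from values up to 0.91 to values near 0, and chromosome 13 lies below 0 throughout.

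The MK2 cultures differed from each other more than the MK1 cultures did. Among 8912 genes at a mean of 10 CPM or more, 106 differed by more than 2-fold between the MK2 replicates and 20 between the MK1 replicates. Named after their values were seen, Krt15, a basal and hair-follicle keratin, stood at 27.9 and 0.247 CPM in MK2 replicates 1 and 2, the chemokine Cxcl1 at 5.84 and 79.4 CPM, and the protease inhibitor Slpi at 37.1 and 235 CPM. Il1a, a cytokine stored in keratinocytes, stood at 5.13 and 73.4 CPM. Its higher level in MK2 was called with all libraries (adjusted p = 0.0284) but not without MK2 replicate 2 (log2 change 0.75, adjusted p = 0.164), MK1 replicate 1 (adjusted p = 0.117) or MK1 replicate 2 (adjusted p = 0.165), nor with the replicate block (adjusted p = 0.124, and 0.122 with the length trend removed). Of 13 tested inflammatory cytokines and chemokines, 2 rose and 5 fell (camera adjusted p = 0.312; median -0.78 and mean 0.03 differed in sign), and without MK2 replicate 2 the list was called lower (median -1.96, adjusted p = 0.0190). The ribosomal RNA precursor Rn45s, chosen after its values were seen, stood at 2569 and 749 CPM in MK2 and at 507 and 630 CPM in MK1.

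The most abundant transcripts by TPM were Eef1a1, Krt14, Krt5, Ppia and the ribosomal protein genes Rps2, Rplp1, Rplp0, Rps12, Rps18 and Rpl41. Of these 10 only Rps2 and Rpl41 were called higher in MK2, by 0.63 and 0.53 on the log2 scale, and both calls ended without MK1 replicate 1 (adjusted p = 0.0641 and 0.0746), that of Rpl41 also with the replicate block and the length trend removed (adjusted p = 0.0618). Rplp1 was called higher without MK2 replicate 2 (log2 change 0.29, adjusted p = 0.0442) and Ppia with the crossed block (log2 change 0.29, adjusted p = 0.0307). Reads of such genes may be shared with pseudogenes.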

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

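The crossed block, the GC trend and 2 list alternatives were chosen after the data had been seen. The numbers of called genes, lists and chromosomes kept within 1.5 times their values under other scalings, filters, tools, length and GC trends and thinning, except as follows. With 1 library left out, the lone culture being assumed to vary like the other line, called genes ranged from 3716 to 6847 (1527 to 3222 higher, 2189 to 3625 lower) and those beyond 2-fold from 985 to 1717 (196 to 431 higher, 789 to 1300 lower), with the lowest counts without MK1 replicate 1. Of 6760 calls testable without it, 0 changed sign. The same held for 0 of 6785 without MK1 replicate 2, and for 0 of 6806 and 0 of 6801 without MK2 replicates 1 and 2. In 100% of the called genes, both cultures of 1 line lay above both of the other. Leaving out 1 library could therefore hardly turn a sign, so these counts of 0 do not show that the calls were stable. With an MK1 library left out, the spread between cultures came from the MK2 pair alone. That pair differed more, with 106 of 8912 genes beyond 2-fold between replicates against 20 in MK1. A call that ended without an MK1 library therefore need not rest on that library, and the cause was not tested further. At an adjusted p under 0.01, 4409 genes were called (1944 higher). Beyond 2-fold, DESeq2 with a log2 threshold of 1 called 1106 (251 higher), and an adjusted p with an estimated fold over 2 called 2851 (897 higher, 1954 lower). Lists numbered 0 with an estimated correlation and 15 against random lists, which ignore correlation between genes; chromosomes numbered 0 with an estimated correlation. Signs turned only in named genes that had not been called: Krt5 (-0.19 to 0.14 with 1 library left out, 0.0054 with the length trend removed, 0.083 with the GC trend removed), Krt14 (-0.20 to 0.069 with 1 library left out, 0.036 without the GC trend), Eef1a1 (-0.027 to 0.29 with 1 library left out), Rplp0 (0.015, GC trend), Rps12 (-0.014 with and -0.016 without the block, length trend) and Rps18 (-0.025 in both); the cause was not tested. The labels do not say whether the replicate numbers pair the lines, and a correlation of deviations of -0.15 from 2 cultures per line cannot settle it. The replicate block called 2733 genes higher and 3175 lower, and 8 lists, and the crossed block 3568 and 3886. Depth limits genes below about 0.1 CPM.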

Other observations

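Signalling and matrix genes differed in both directions without a list call by camera. Of 19 tested genes of TGF-beta and BMP signalling, 9 rose and 5 fell (camera adjusted p = 0.211; adjusted p = 0.0342 against random lists, which ignore correlation between genes). The BMP-responsive regulator Id1 rose from 0.413 ± 0.259 to 52.2 ± 12.4 CPM, and Tgfbi and Fst, an activin antagonist, rose by 4.04 and 3.84 on the log2 scale. Of 20 tested matrix and protease genes, 6 rose and 7 fell (camera adjusted p = 0.964; median -0.28 and mean 0.36 differed in sign). The protease inhibitors Timp3 and Timp1 rose to 29.4 ± 18.2 and 103 ± 30.6 CPM, while Plau and Timp2 had log2 changes of -1.48 and -1.45. Of 7 tested fibroblast genes, 2 rose and 4 fell (camera adjusted p = 0.411; adjusted p = 0.0467 against random lists): the collagen genes Col6a1 and Col6a2, neighbours on chromosome 10, fell from 66.7 ± 15.2 and 23.4 ± 1.43 CPM to 0.287 and 0.110 CPM, and Col5a2 stood at 9.34 CPM in MK2 with 2 counts in MK1. Of 10 tested genes of epithelial-mesenchymal transition, 3 rose and 4 fell (camera adjusted p = 0.411), and the transcription factors Twist1 and Zeb1 fell from 36.3 and 3.37 CPM to 1.22 and 0.130 CPM. Of 18 tested epithelial transcription factors, 4 rose and 9 fell (camera adjusted p = 0.211), with Elf3 falling from 24.1 ± 0.160 to 1.60 ± 0.632 CPM. In the WNT list 4 of 19 rose and 7 fell (camera adjusted p = 0.50): the receptor Fzd10 stood at 13.6 CPM in MK1 with 3 counts in MK2, Rnf43 fell by 4.27 and Dkk3 rose by 5.81.

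Stress and metabolic lists were also mixed. Of 21 tested antioxidant genes, 8 rose and 7 fell (camera adjusted p = 0.954), with the cystine transporter Slc7a11 rising from 6.51 ± 1.83 to 74.7 ± 11.1 CPM and Gstm4 going from 4.44 CPM to 0 counts. Of 18 genes of the unfolded-protein and integrated stress responses, 6 rose and 2 fell (camera adjusted p = 0.499), with the chaperone Hspa5 higher by 1.25 and Herpud1 changed by -1.74. Of 22 hypoxia and glycolysis genes, 8 rose and 7 fell (camera adjusted p = 0.50), among them Pdk1, which rose by 2.01, and Egln3, which fell by 3.29. Immediate-early genes (1 of 16 rose, 8 fell, camera adjusted p = 0.211; adjusted p = 0.0493 against random lists), EGFR ligands and signalling (4 of 16 rose, 7 fell, 0.598), Notch (3 of 13 rose, 4 fell, 0.623), hair follicle (2 of 8 rose, 1 fell, 0.663), the epidermal differentiation complex (5 of 13 rose, 4 fell, 0.50), Merkel and neural (0 of 5 rose, 3 fell, 0.352) and muscle (1 of 5 rose, 1 fell, 0.598) were not called by camera. The muscle gene that rose was Acta1, at 5.01 and 72.6 CPM in MK2 replicates 1 and 2, and 0 muscle genes rose when adjusted over the list alone. Its log2 change was 3.15 with all libraries and 0.19 without MK2 replicate 2. Of the lists too small for camera, melanocyte genes had 1 of 3 falling, endothelial genes 1 of 3 rising and 1 falling, and sebaceous and adipocyte genes 2 of 4 falling, Scd1 among them (log2 change -2.94).

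In the 3 patterns that follow, the tests of near neighbours and strain variants and the bootstrap intervals were chosen after the result was seen, and the pattern of B-cell transcripts was itself found in these data. Chromosome-wide shifts were not removed by correcting for GC content or gene length: the median size of the called shifts was 107.3% and 96.64% of its size before. Co-regulation of near neighbours alone was argued against, because genes more than 20 Mb apart on a chromosome were alike in fold change (mean product of standardised ranks 0.06236, against at most 0.0222 in 1000 shuffles of 20 Mb blocks, which keep near neighbours together). Copy number differences and chromosome-wide regulation remain untested: a test of copy number had been run only on the chromosomes called for their shift, which decides nothing, and it was dropped. DNA was not analysed here.

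For the lower p53 targets, placement on chromosomes that are lower in MK2 was argued against as the whole cause by the size of the whole-chromosome shifts. The lowest chromosome median was -0.41 (chromosome 13), against a list median of -0.97. Parts of chromosomes were lower, with medians of -0.65 in a run on chromosome 13 and -1.09 in the last 29 tested genes of chromosome 2. Placement in such parts was not tested. With each gene's chromosome median subtracted, the list median was -0.748 (camera adjusted p = 3.28e-05, and 0.579 with an estimated correlation). Its bootstrap 95% interval of -1.28 to -0.60, which treats genes as independent, did not lie wholly below the bound of -0.73 set for excluding placement. The value of -0.49 set in favour of placement was out of reach of the whole-chromosome medians that were subtracted, so missing it decides nothing. A second list of p53 targets, with no gene in common and written before its values were seen, had 18 of 22 tested genes lower and 0 higher (median -0.7317, camera p = 1.07e-05; p = 0.0401 with an estimated correlation). Lower p53 activity in MK2 is thus a hypothesis that passed a test it could have failed, and what lowered the targets was not tested.

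For leukocyte and MHC class II transcripts in MK1, strain variants in the H2 region (chromosome 17) were argued against only as the whole cause. Ciita, Cd74 and Ptprc, all lower in MK2, lie on chromosomes 16, 18 and 1, and such variants would not touch their reads. Of 5 antigen-presentation genes outside chromosome 17, 3 were lower in MK2 (Nlrc5, Ciita and Cd74, but not B2m or Psmb10). Ciita and Cd74, both B-cell genes, were already known to be lower when that count was planned, and without them it was 1 of 3. The count therefore decides nothing, and variants remain open for the H2 genes themselves. Leukocytes in the cultures cannot be told apart from other sources by the bound of 0.5 written before. The median of 12 abundant leukocyte transcripts was 0.253 and 0.3594 times Ptprc in MK1 replicates 1 and 2, which met the bound for excluding leukocytes. The bootstrap 95% intervals added later, 0.0647 to 1.17 and 0.0703 to 1.13, did not meet it. The 3 myeloid genes among the 12 (Tyrobp, Fcer1g and Lyz2) were at most 0.0235 and 0.0625 times Ptprc. The median of the other 9 was 0.376 and 0.375 times Ptprc. Of the 12, 10 exceeded 3 counts in MK1 at 5 times the MK2 level or more. Srgn, Lyz2 and Cd48, among these, had too few counts to be tested. Lcp1, Arhgdib, Coro1a and Rac2 (4 of the 12) exceeded Ptprc in both MK1 libraries. RNA of B lymphocytes is a candidate explanation: of a second list of 20 B-cell genes, written before its values were seen, 15 exceeded 3 counts in MK1 at 5 times the MK2 level or more, Cd22 among them at 2.86 and 3.13 CPM, against 1 of 14 T-cell genes. Where such RNA came from, and how much of the MHC, leukocyte and interferon differences it carries, was not determined.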
